A study of Drosophila melanogaster with 2 samples.

How the data were processed

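The series measured where the protein ATbp lies on DNA in Drosophila melanogaster embryos. Per the labels, a transgenic line expressed ATbp with a green fluorescent protein tag at its C-terminal end, and chromatin from whole embryos of both sexes, collected from 0 to 14 h of development, was immunoprecipitated with an antibody against the tag. The labels give sonication to fragments of 200 to 800 bp and 2 biological replicates, which form 1 group. No control library was analysed here.

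The deposited files are peak lists. Per the labels, each replicate has a relaxed list made as input for an irreproducible discovery rate (IDR) analysis, a further relaxed list comes from the pooled alignments of both replicates with a control, and an IDR thresholded list comes from the replicates together. Each exists on the genome builds dm6 and dm3. The signal value of a peak is the authors' own, as deposited. It was used here to rank, describe or filter peaks within 1 list, and in 1 correlation of log10 signal between the replicates. The deposited column of significance was read as the −log10 of a q-value from the file format, with the p-value column left unfilled by the authors. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. The files give no read counts, so the depth of each library is unknown and its effect on peak number could not be measured. Intervals on shares cover counting error only.

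Coordinates are those of dm6, written 1-based, and were set against the reference assembly of the same release and Ensembl annotation release 115 (BDGP 6.54). Transposable elements were left out of the genes. This gave 24111 transcription start sites (TSSs) of 18277 genes. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 were used.

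The number N of dm6 IDR peaks was 5921. Replicates were compared by the share of the N strongest replicate 1 summits within 100 bp of one of the N strongest replicate 2 summits, against 1000 circular shifts along each chromosome. Ranks were compared by Spearman's rho with 100000 permutations. Promoter peaks were summits within 500 bp of a TSS, tested against 1000 shifts. Chromosome shares were tested with exact binomial tests on 7 chromosomes, and 7 annotation classes with the shifts. A summit took the first class that applied of promoter, 5' UTR, coding sequence, intron, 3' UTR, other exon and intergenic. The classes after promoter therefore hold only summits farther than 500 bp from a TSS. A+T content was taken in 101 bp around each summit and compared with 1 window per peak, outside every relaxed pooled peak, of the same chromosome and annotation class. For 16 preset motifs and all 6-mers, with reverse complements merged, the windows were also matched on A+T content to within 2 percentage points, which 99.98% of them met, and Fisher's exact test was used. For 26 gene lists, members with a promoter peak were compared with other protein-coding genes, or with all other genes for tRNAs, by Fisher's exact test. Adjusted p-values are Benjamini-Hochberg values within each family, and tests are two-sided unless stated.

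Designs, lists, motifs and most alternatives were fixed before the data were examined. Matching promoter windows also on TSS distance, within 50 bp, was added later. The position of ACAGTG was looked at without a design. After the 6-mer results, distances from the summit were viewed for 6 6-mers, strand profiles for 4 sequences, and 6-mers to 8-mers beside summits were ranked. ACAGTG and a zone of 50 to 125 bp were then kept, so its counts carry no correction for this search and no p-value is given for them. Repeating the draw of matched windows 100 times was added after 2 draws had been seen to give different motif calls. The draw whose seed had been set first was kept as the main one, and the number of draws in which each motif passed is given beside its call.

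Named genes are ATbp; every gene with a TSS within 500 bp of the summit of the 10 strongest IDR peaks, or else the gene holding or nearest the summit; the 3 members with the strongest promoter peaks of each list past 0.05 adjusted, or up to 3 bound members of a depleted list; and the 1 strongest member of every other list.

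The tests were tested on simulated data. Random summits gave a promoter p under 0.05 in 6 of 100 runs and an overlap p under 0.05 in 8 of 100 runs. A planted promoter share of 39.8% was recovered as 38.7%. All 20 6-mers planted among 2080 were recovered, and 0 passed where nothing was planted. Bound genes drawn at random gave a list past 0.05 in 2 of 100 runs. Random summits were spread evenly along the chromosomes, unlike real peaks, and were tested with fewer shifts than in the analysis. Genes were drawn independently and the tRNA list was left out, so shared promoters and clustered genes were not simulated.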

Results

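ATbp-bound regions were mapped in 2 biological replicates of whole embryos aged 0 to 14 h. ATbp is a zinc finger protein named for binding A+T-rich DNA. Each replicate's relaxed list held 30000 peaks on both builds, as did the pooled list. The same count in every relaxed list looks like a set limit, so it does not compare the yields of the libraries. The IDR list held 5921 peaks on dm6 and 5364 on dm3. All 5921 dm6 IDR peaks were the 5921 strongest peaks of the pooled list by the authors' signal value. Their signal ran from 128.5 to 4854.3 with a median of 220.5, and 3718 of them were 404 bp wide. Several summits fell in 1 interval in places, so the list held 5904 distinct intervals.

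The strongest IDR peak lay at the promoter of the noncoding RNA gene lncRNA:CR31840 on 2L, with its summit at 14024074, 25 bp from the TSS, and a signal of 4854.3. It ranked 1 in replicate 1 and 2 in replicate 2. Promoters of Ugalt, a UDP-galactose transporter gene (X, summit 2703879, signal 3766.8), px (2R, summit 22514298, signal 3270.3) and CG14100 (3L, summit 19590614, signal 3045.9) ranked 2, 4 and 8. The peaks ranked 3, 5, 6, 9 and 10 lay in introns of cno, a gene of cell junctions, CG11050, ush, a gene for a cofactor of GATA factors, sbb and CG32772. The peak ranked 7 was intergenic, at 13035334 on 2R, and CG13323 was the nearest gene.

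The first comparison asked how far the replicates found the same regions. Of the 5921 strongest replicate 1 summits, 4101 (69.3%, Wilson 95% interval 68.1 to 70.4) lay within 100 bp of one of the 5921 strongest replicate 2 summits. Shifted summits gave 0.892% ± 0.124 (SD, 1000 shifts), with a one-sided permutation p of 0.001, the smallest the shifts can give. Among the strongest 500 peaks the share was 76.4%, and over all 30000 it was 44.2%. Of the IDR summits, 5481 (92.6%) had a relaxed peak within 100 bp in both replicates, 268 in replicate 1 alone, 164 in replicate 2 alone and 8 in neither. The IDR list was made from these replicates, so the 92.6% is largely built in and is no separate measure of their agreement. Signal ranks at the 5481 shared summits had a Spearman rho of 0.698 (permutation p = 1e-05, the smallest the resamples can give). Pearson r was 0.369 on ranks in the full replicate lists and 0.766 on log10 signal. These are correlations across peaks, which are not independent replicates.

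**Figure D1:**
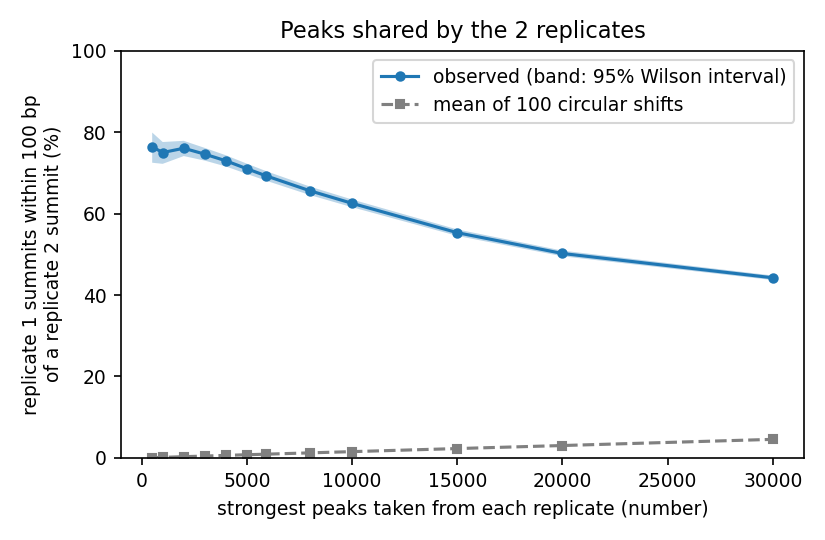
Share of replicate 1 summits (%) within 100 bp of a replicate 2 summit, against the number of strongest peaks taken from each replicate, with the 95% Wilson interval as a band and the mean of 100 circular shifts as squares. The share was 76.4% at 500 peaks and 44.2% at 30000, and the shifts gave 4.54% there.

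Promoters and introns held most of the IDR summits. Of 5921 summits, 2051 (34.6%, Wilson 95% interval 33.4 to 35.9) were within 500 bp of a TSS, against 13.6% ± 0.668 (SD) in shifted positions, a ratio of 2.55 (permutation p = 0.001, the smallest the 1000 shifts can give). Introns held 2782 summits (47.0%, 1.17 times the shifted mean, but below the 48.9% of the weakest 10000 relaxed peaks) and intergenic DNA 921 (15.6% against 27.2%). Farther than 500 bp from a TSS, coding sequence held 20 summits, 0.338% against 13.7%, with 4.57% in the weakest 10000 relaxed peaks. The 3' UTRs there held 59, 0.996% against 4.09%, with 2.3% in those weakest peaks. These 5 classes had an adjusted permutation p of 0.0014. Neither 5' UTRs farther than 500 bp from a TSS (0.676% against 0.780%, adjusted permutation p = 0.416) nor other exons (0.811% against 0.607%, 0.0909) passed. The promoter share was 51.6% in the strongest 500 peaks, 30.1% past rank 4000 and 15.8% in the weakest 10000 relaxed peaks.

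**Figure D2:**
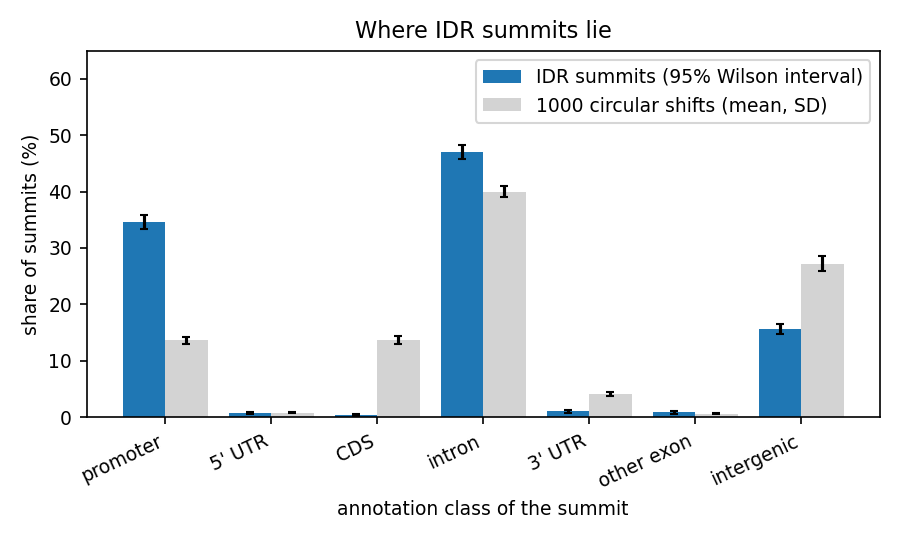
Share of IDR summits (%) in each annotation class, with 95% Wilson intervals, beside the mean and SD of 1000 circular shifts. Promoters, which took priority over the other classes, held 34.6% against 13.6%, and coding sequence 0.338% against 13.7%.

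Peak density differed between chromosomes. Chromosome 4, the small and largely heterochromatic chromosome, carried 14 peaks where its length gave 58.0 (ratio 0.241, exact binomial adjusted p = 3.16e-11). The arm 2L carried 1104 against 1012.2 (1.09, 0.00392) and X carried 1096 against 1013.4 (1.08, 0.00816). The Y chromosome had 0 peaks against 157.9 (exact binomial adjusted p = 3.77e-69), and how much of it reads can be placed on is unknown here. The relaxed dm6 lists of both replicates and of the pool held no peak there either. The Y test can therefore not tell missing signal from reads that could not be placed. The length of Y was part of the total, which lowers the expected peaks of every other chromosome and raises their ratios. Whether 2L and X would pass without Y was not tested. Arms 2R, 3L and 3R had ratios of 0.962, 1.04 and 1.01 and did not pass. Against the weakest 10000 relaxed peaks no chromosome passed, with chromosome 4 at 0.844 and 2L at 0.973, and X did not pass in replicate 1 alone (1.03, exact binomial adjusted p = 0.327).

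DNA under the summits was richer in A and T than matched DNA. The 50 bp to either side of IDR summits, with the summit base, held 64.7% A+T ± 9.26 (SD, 5921 windows) against 58.9% ± 9.86 in windows of the same chromosome and class, a difference of 5.82 percentage points (SE 0.176, permutation p = 1e-05, the smallest the resamples can give). The difference was 7.13 points at promoter summits, 4.95 in introns and 5.87 in intergenic DNA. A run of at least 8 A or T bases lay in 70.9% of summit windows and 54.7% of these control windows (odds ratio 2.02, Fisher's exact p = 9.77e-75). Around the summits A+T content fell from 65.5% in the central 40 bp to 57.2% at a distance of 200 bp upstream in coordinates. Peaks with higher signal had more A+T, with 67.1% in the strongest 500 and 63.4% past rank 4000.

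**Figure D3:**
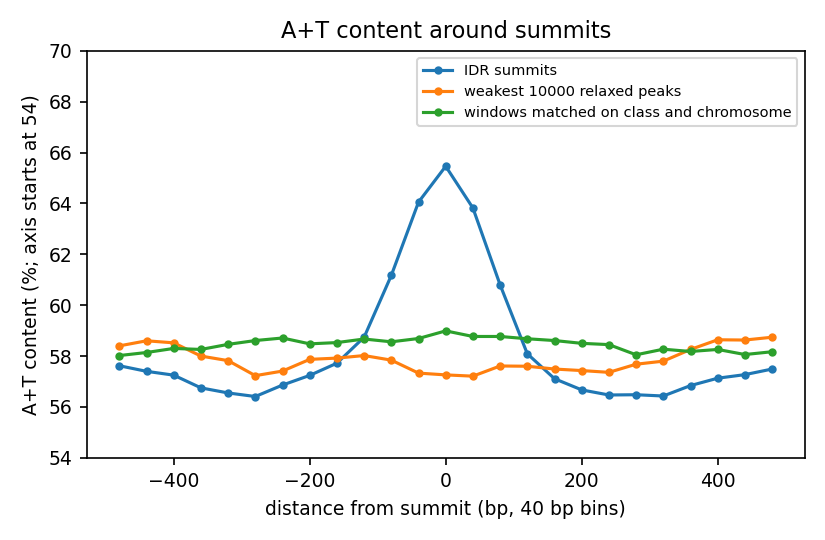
Mean A+T content (%, axis from 54) in 40 bp bins by distance from the summit (bp), for IDR summits, the weakest 10000 relaxed peaks and windows matched on class and chromosome. The central bin stood at 65.5%, 57.3% and 59.0% in these sets.

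The insulator motif of CTCF stood out among 16 preset motifs once A+T content was matched. Its core occurred in 35 summit windows (0.591%) and 5 control windows (0.0845%), an odds ratio of 7.04 (Fisher's exact test, adjusted p = 1.07e-05), and passed in 100 of 100 draws of control windows. The size is poorly fixed, since 5 control windows carry it: across draws the odds ratio ran from 3.20 to 71.4. It was 4.45 in replicate 1 alone, 2.37 against the weakest 10000 relaxed peaks and 3.06 against windows 400 to 500 bp away, passing each time. Of the 35, 10 were at promoters, 13 in introns and 7 intergenic. CA repeats were in 2.38% of summit and 1.37% of control windows (1.76, exact adjusted p = 0.000311), passing in 97 draws, and runs of 6 A were rarer at summits, 23.6% against 27.7% (0.805, adjusted p = 4.5e-06), passing in 95. The direction of these 2 depended on the control: against the weakest 10000 relaxed peaks the odds ratios were 0.729 for CA repeats and 1.28 for A runs. Those peaks and the windows 400 to 500 bp away were not matched on A+T, at 57.2% and 57.4% against 64.7% at IDR summits. The reversal of A runs can therefore not be told apart from the difference in composition. In replicate 2 alone neither CA repeats (1.25, exact adjusted p = 0.272) nor A runs (0.908, 0.0515) passed.

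The GAGA motif missed the threshold in the main draw (1.76% against 1.22%, odds ratio 1.45, exact adjusted p = 0.0586) and passed in 99 of the 100 draws, with a median odds ratio of 1.84. GAGA also passed with TSS distance matched (1.61, exact adjusted p = 0.0125), in replicate 1 alone (1.89, 7.32e-05) and with 100 bp either side (2.03, 2.38e-10). It did not pass in replicate 2 alone (1.535, exact adjusted p = 0.0515), in the stronger IDR peaks (1.19, 0.804) or against the weakest 10000 relaxed peaks (1.03, 0.907). Against windows 400 to 500 bp from the same summits, not matched on A+T, its odds ratio was 0.634. Ohler motif 7, a core promoter element, had an odds ratio of 1.60 (exact adjusted p = 0.0586) and passed in 73 draws. With control windows matched also on TSS distance it did not pass (1.21, exact adjusted p = 0.525). The DNA replication-related element passed in 36, Motif 1 in 17 and the Su(Hw) core in 5, always as higher at summits. The initiator passed in 16, Ohler motif 6 and TA repeats in 2 each, and A/T runs of 8 in 1, always as lower at summits. The short DRE, the Zelda motif, the TATA box and the E-box passed in 0 draws. Once A+T was matched, A/T runs of 8 were in 70.9% of summit and 72.4% of control windows (exact adjusted p = 0.194).

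Many 6-mers differed at summits. Of 2080 tested, 381 passed an adjusted p of 0.05 by Fisher's exact test, 179 higher and 202 lower, and 76 passed in every one of 100 draws, 50 higher and 26 lower. CGTACG had the highest odds ratio, 2.89, in the main draw, and passed in 26 draws. ACAGTG (7.03% of summit against 3.56% of control windows, odds ratio 2.04), GTGCAC (2.17), GTACAC (2.01), GTAAAC (1.98) and CAAACA (18.3% against 10.2%, 1.97) passed in all 100. CCAGGA was the lowest, at 0.777% against 2.62% (0.291), and also passed in all 100. The position of ACAGTG was examined after its values were seen, and it was picked after distances of 6 such 6-mers, strand profiles of 4 sequences and a scan of 6-mers to 8-mers beside summits had been viewed. Matches on the plus strand were most numerous 80 to 100 bp left of the summit, at 116 per 20 bp, and those on the minus strand 80 to 100 bp right of it, at 136.

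**Figure D4:**
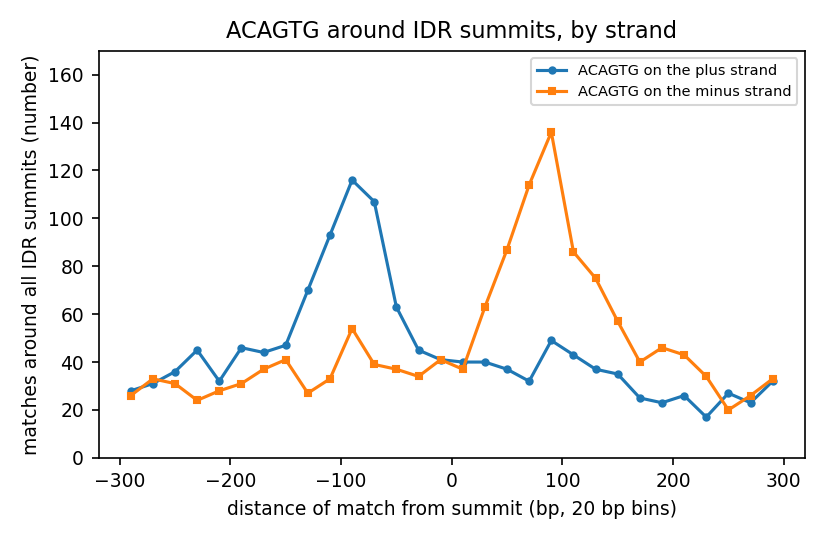
Number of ACAGTG matches in 20 bp bins by distance from the IDR summit (bp, negative to the left in coordinates), for the plus and minus strands. The highest bins held 116 plus strand matches to the left and 136 minus strand matches to the right.

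Genes of cytosolic ribosomal proteins carried promoter peaks far more often than other genes. Of 85, 60 had one (70.6%, Wilson 95% interval 60.2 to 79.2), against 2018 of 13883 other protein-coding genes (14.5%), an odds ratio of 14.1 (Fisher's exact test, adjusted p = 1.3e-29). RpL7 (2L, summit 10201036, rank 131), RpS27 (3R, summit 25247506, rank 172) and RpL14 (3L, summit 8600989, rank 339) had the strongest, with summits 32, 8 and 17 bp from a TSS. The windows around these 3 summits held 40.6%, 51.5% and 54.5% A+T, below the mean of 64.7% at IDR summits. A+T content at the other ribosomal protein summits was not summarised. Mitochondrial ribosomal protein genes had 12 of 73, led by mRpS23 (rank 16), and translation factor genes 13 of 51, led by eIF6 (rank 108), with adjusted p-values of 0.963 and 0.108. Translation factor genes passed with a narrower promoter (odds ratio 2.49, exact adjusted p = 0.0405) and among genes with a relaxed promoter peak (13 of 15, 8.99, exact adjusted p = 0.00669), where mitochondrial ribosomal protein genes did not (12 of 26, 1.18, 0.877). That filter depends on the outcome, since all IDR peaks are also relaxed pooled peaks, and it drops 36 translation factor genes. Translation factor genes did not pass with promoters of 1000 bp (exact adjusted p = 0.258), in the stronger IDR peaks (0.106), in replicate 1 alone (0.0702), in replicate 2 alone (0.241) or with shared promoters merged (0.0714).

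Lists with fewer promoter peaks were chemoreceptor, cuticle, male accessory gland, histone and oxidative phosphorylation genes. Chemoreceptor genes had 0 of 179, which allows a share of up to 2.10% (Wilson upper limit, exact adjusted p = 6.49e-12). Cuticle genes had 1 of 118, Cpr65Av (exact adjusted p = 1.47e-06). Male accessory gland genes had 1 of 47, Sfp26Ad (exact adjusted p = 0.0311), with an odds ratio of 0.124. The call was lost with promoters of 1000 bp (0.294, exact adjusted p = 0.0800), with shared promoters merged (0.140, 0.0616) and in the stronger IDR peaks (0.109, 0.0942). Histone genes had 2 of 115, the single-copy variants His2Av and His3.3B (exact adjusted p = 2.64e-05), and whether reads could be placed on the repeated histone genes is unknown. Oxidative phosphorylation genes had 4 of 84, led by ND-ASHI, ND-24 and ATPsynE (odds ratio 0.285, exact adjusted p = 0.0276), a call lost in replicate 1 alone (0.497, 0.202) and replicate 2 alone (0.516, 0.218). The oxidative phosphorylation call was also lost with a narrower promoter (0.297, exact adjusted p = 0.0588) or one of 1000 bp (0.454, 0.0986), with shared promoters merged (0.399, 0.0967) and among genes with a relaxed promoter peak (0.304, 0.124). Among genes with a relaxed promoter peak 3 histone and 2 accessory gland genes remain, of which 2 and 1 had an IDR peak, too few to give a direction.

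Among the other 20 lists none passed in the main comparison, and 7 passed in some alternatives. Architectural protein genes had 7 of 19, led by Chro (rank 17), with an odds ratio of 3.35 (exact adjusted p = 0.0578), and passed in either replicate alone (0.00422 and 0.0490). It also passed with a narrower promoter (3.72, exact adjusted p = 0.0448), with shared promoters merged (4.05, 0.0301) and in the stronger IDR peaks (4.82, 0.0233). It did not pass with promoters of 1000 bp (2.53, exact adjusted p = 0.164) or among genes with a relaxed promoter peak (1.93, 0.761). Polycomb and trithorax group genes had 7 of 26, led by ph-p (rank 15, exact adjusted p = 0.177), heat shock genes 6 of 19, led by Hsp27 (rank 47, 0.108), and Notch and E(spl) genes 6 of 18, led by E(spl)m3-HLH (rank 660, 0.105). Muscle genes had 6 of 23, led by tin (rank 588), dorsoventral patterning genes 4 of 16, led by ush, cell cycle genes 4 of 30, led by Dp, and neural genes 3 of 21, led by elav (rank 106). Segment polarity genes had 2 of 15, led by nkd, the hemocyte and fat body list 2 of 15, led by ush, the proteasome 2 of 48, led by Rpn5, maternal and gap genes 1 of 11, bcd, and germline genes 1 of 12, gcl. Notch and E(spl) genes passed as higher with promoters of 1000 bp (3.47, exact adjusted p = 0.0412) and in replicate 1 alone (3.50, 0.0445), and Polycomb and trithorax genes with shared promoters merged (3.37, 0.0290). The proteasome passed as lower with promoters of 1000 bp (0.188, exact adjusted p = 0.0242) and in replicate 1 alone (0.116, 0.0204), as did the proteases (0.0785, 0.0242 and 0.0994, 0.0458). Hox genes had 0 of 8, pair-rule genes 0 of 9 and trypsin-like and Jonah proteases 0 of 27. The chorion, vitelline membrane and yolk list had 1 of 22, Cp190, which is an architectural protein gene that the preset name pattern also took in.

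Transfer RNA genes went in opposite directions in the replicates. In the IDR list 27 of 295 had a promoter peak (9.15%), led by tRNA:Tyr-GTA-1-8 (rank 87), against 13.0% of other genes (Fisher's exact test, adjusted p = 0.108), and the 27 genes share 19 peaks. The IDR list gave fewer with a narrower promoter (odds ratio 0.408, exact adjusted p = 0.00418) and among genes with a relaxed promoter peak (0.324, 9.36e-08). The relaxed-peak filter depends on the outcome, since IDR peaks are also relaxed pooled peaks. It kept 154 of 295 tRNA genes and 5920 of 17982 others, so that value is no separate sign of fewer IDR peaks at tRNA genes. With shared promoters merged the odds ratio was 0.819 (exact adjusted p = 0.652). The strongest 5921 peaks of replicate 1 gave 60 (20.3%, odds ratio 1.63, exact adjusted p = 0.00762) and those of replicate 2 gave 21 (7.12%, 0.509, adjusted p = 0.00692). These replicate tests count tRNA genes that share a peak as separate genes, and shared promoters were not merged in either replicate alone. The difference between the replicates was not tested.

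**Figure D5:**
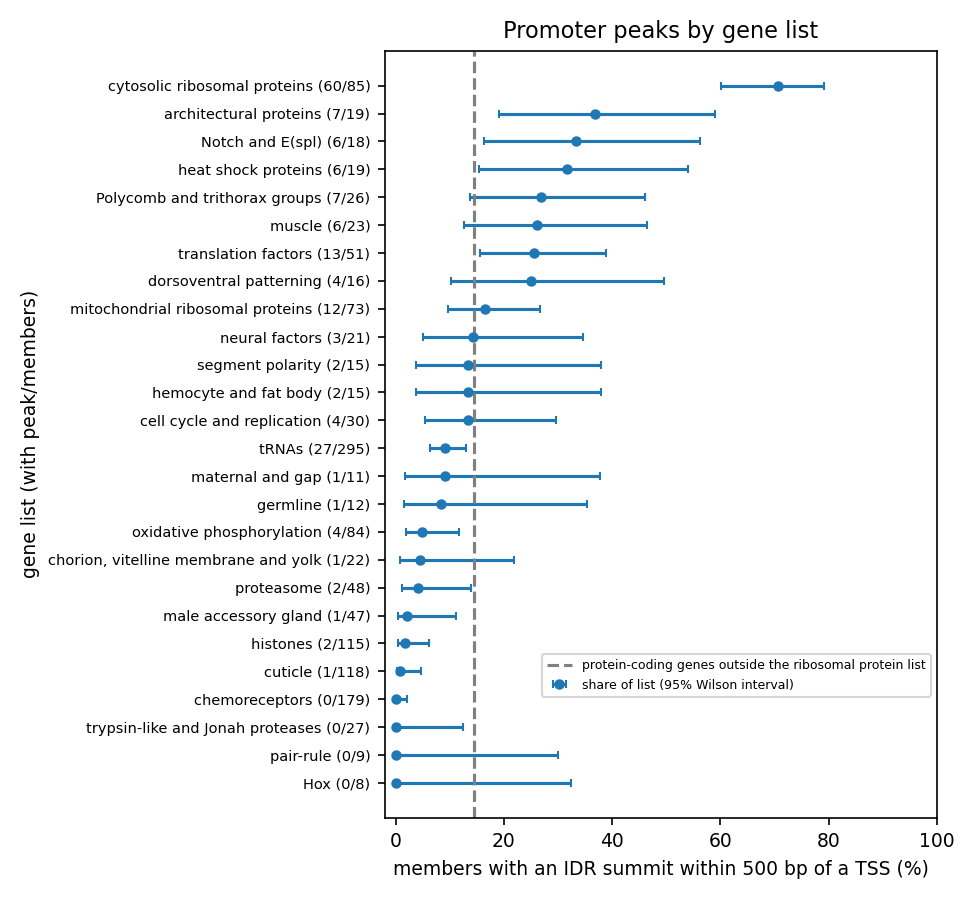
Share of each gene list (%) with an IDR summit within 500 bp of a TSS, with 95% Wilson intervals, and the share of protein-coding genes outside the ribosomal protein list as a dashed line at 14.5%, which is not the comparison used for tRNAs. Cytosolic ribosomal proteins stand at 70.6% and chemoreceptors at 0%.

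The gene ATbp itself (X, 23106003 to 23108331) had no IDR summit in it or at its TSS. Within 20 kb there was 1 IDR summit, at 23096275, with rank 4844, within 500 bp of TSSs of CG17162 and su(f), and it was 9.73 kb from ATbp. The pooled relaxed list had 1 peak there against 9.50 ± 8.55 (SD) in 1000 random windows (one-sided permutation p = 0.844), and the replicates had 1 and 2. Of the 30 named genes with a promoter peak, 25 had one among the strongest 5921 peaks of both replicates. These genes were named for IDR peaks drawn from the same replicates, so this is not a separate check. Of all IDR summits, 4110 (69.4%) had a peak within 100 bp among the strongest 5921 of both replicates.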

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

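The dm3 lists hold peaks on heterochromatic and unplaced sequences, which the comparisons above do not use. Replicate 1 had 5 such relaxed peaks and replicate 2 had 49, each above the 3 that a count of 0 allows. In replicate 2, 14 were on the heterochromatic part of 2R, 13 on that of 3L and 10 on that of 3R. The pooled list had 9 and the IDR list 2. An exact binomial test of an even split between the replicates gave p = 3.89e-10, which covers counting error only, with 1 library on each side and depth unknown.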

How the results depend on the processing

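The 100 repeated draws and the TSS-distance matching were chosen after the data were seen. Of 57 alternative values for the main results, 47 kept their direction and side of the threshold or stayed within 1.5 times the main count, and 10 counts moved; the cause was not tested. Replicate overlap ran from 44.2% to 75.2%, the promoter share from 24.4% to 46.2% and the A+T difference from 4.29 to 7.46 points, past the threshold each time. The 381 6-mers became 157 in the stronger IDR peaks, 1443 against the weakest 10000 relaxed peaks and 1500 against windows 400 to 500 bp away, where A+T was not matched. The 3 motifs became 10 against each of those backgrounds, 5 with TSS distance matched, 8 in the highest of 100 draws, and 4 to 6 with a replicate left out. The 4 chromosomes, with Y among them, became 0 against the weakest 10000 peaks. The 6 gene lists became 7 to 10 with a replicate left out.

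Some single items reversed. Against the weakest 10000 peaks these were 2L (ratio 0.973), A runs (odds ratio 1.28) and CA repeats (0.729). Against windows 400 to 500 bp away they were A runs (1.27), CA repeats (0.657) and GAGA (0.634), and with 100 bp either side A runs (1.01). The weakest peaks and the windows 400 to 500 bp away were not matched on A+T. Among genes with a relaxed promoter peak they were histones (2.75, 3 genes left) and the accessory gland list (1.38, 2 genes left). With a replicate left out the tRNA odds ratio ran from 0.509 to 1.63. Of the other values for single items, 152 were labelled as unchanged, 17 as weaker and 25 as stronger. The unchanged and weaker ones include promoter peak ranks of named genes, which carry no test, and most of these genes were named for an IDR peak from the same replicates. The unchanged ones also include items that passed neither in the main comparison nor in the alternative. ND-24 and gcl had no replicate 2 peak at the promoter, so no rank could be given there. No paired analysis was possible because there is 1 group. Library depth is unknown, which limits any comparison of peak numbers.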

Other observations

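Replicate 1 peaks without a partner differed in composition from those with one. The 1820 unpaired replicate 1 peaks held 59.0% A+T and 40.8% lay at promoters, against 65.3% and 34.6% for the 4101 paired ones. The 1820 unpaired replicate 2 peaks held 65.2% A+T and 32.4% lay at promoters. Unpaired peaks were also weaker, with a median rank of 4409 against 2185 for paired ones in replicate 1 and 4521.5 against 2158 in replicate 2. Rank was not held equal, and no test of these differences was run. A weaker relaxed peak of the other replicate lay within 100 bp of 53.4% of the unpaired replicate 1 peaks and 69.3% of the unpaired replicate 2 peaks.

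Tests of housekeeping promoters, of library base composition and of A+T-rich surroundings were chosen after the values they rest on were seen, as were ACAGTG itself, picked in a search of several sequences, its distance range and its profiles in each replicate and in the weakest peaks. The other tests were set before their own results. The design has 1 group and no control library was analysed here, so no biological explanation from a difference between groups was tested, nor whether any pattern depends on ATbp.

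Ribosomal protein promoters carried peaks in 70.6% of genes. A+T-rich promoters do not account for this, as the odds ratio stratified by 10 classes of promoter A+T was 15.1 (95% interval 9.25 to 24.6). The 4 other housekeeping lists together had peaks at 12.1% of 256 genes (8.66 to 16.7), which argues against housekeeping promoters in general, and the highest of them, translation factors, had 25.5% (15.5 to 38.9), below the ribosomal protein interval of 60.2 to 79.2. The smaller odds ratio from 1 replicate alone was 12.1. Signal at highly transcribed promoters whatever the tagged protein may still be the cause, since neither expression nor a mock immunoprecipitation was analysed here.

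A+T-rich summits are not a property of every called region. The weakest 10000 relaxed peaks of the pooled list differed from their own matched windows by -1.61 points. This argues against the base composition of the pooled libraries, but cannot show a bias of 1 library. The excess at the strongest summits was 4.6 points in replicate 1 alone and 6.5 in replicate 2 alone. Windows 400 to 500 bp from the summits differed by -1.46 points, which argues against A+T-rich surroundings. Binding of ATbp to A+T-rich DNA may account for the excess, and open chromatin of that composition stays open as untested.

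A hypothesis from the 6-mers is that an oriented element lies beside an A+T-rich centre. In the zone kept beside IDR summits, 762 ACAGTG matches pointed at the summit and 304 away (ratio 2.51), against 353 and 314 at the weakest 10000 peaks, and the ratio was 2.38 in replicate 1 and 2.67 in replicate 2. The share of matches pointing at the summit whose 41 bp context recurred exactly was 0%, which argues against repeated sequence in exact copies and says nothing of diverged ones. Away from TSSs the ratio was 2.52, which argues against core promoter orientation. A second protein, or a fixed offset between the element and the called summit, may explain it, and these were not told apart by any test run here.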
